A study of Homo sapiens with 4 samples.

How the data were processed

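The series holds 4 Illumina HumanHT-12 v4 arrays: parental HCC827 cells (1 array) and 3 afatinib-resistant lines (BR42, BR16-1 and BR16-2, 1 array each). Samples were grouped by the source name in the labels, and the 3 resistant lines served as the replicates of the resistant group; replicate numbers follow the order of deposit. The labels do not say whether BR16-1 and BR16-2 came from 1 tumour, so the p-values of single probes measure only the spread between these lines. Camera p-values set the genes of a list against all other genes, and those of the closing section rest on shuffled gene orders. Both take genes as their units and do not test agreement between the lines. Per the labels' protocols, 500 ng of total RNA was converted to biotin-labelled material for hybridisation, and the series text names GeneSpring GX for the analysis. The software that summarised the beads and any chip or scan batch are not given in the sources used here, so the chip could not be tested as a batch.

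The authors deposited a probe signal intensity for each array, on a linear scale, named non-normalized per the file headers; its medians and upper quartiles differed between arrays. They also deposited a detection p-value for each signal, which moves in steps of 1 over 770. A further deposited table holds the authors' processed intensity values, also linear. Set against the scanner signals, each of its columns kept the rank order of its own array (rank correlation of 1 after rounding, against at most 0.898 between different arrays), its 4 columns held nearly the same sorted values, and their medians lay between 149.65 and 149.68, so that the scale is linear and quantile normalized; the distribution to which the arrays were matched stays unknown. No 2 arrays held near-identical values.

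From the deposited signals, background correction with negative-control moments inferred from the detection p-values, an offset of 16, quantile normalization and log2 were applied with neqc of limma 3.58.1 in R 4.3.3. The 18695 probes (39.6%) with a detection p under 0.01 on at least 1 array were tested with lmFit and eBayes, resistant minus parental, two-sided, with Benjamini-Hochberg adjustment over all of them. The spread comes from the 3 resistant lines (2 residual degrees of freedom and a prior worth 3.23), and the lone parental array was assumed to vary like them. Files name no genes for probes: a table of the platform's annotation paired 30113 probes with 1 gene symbol, 8 with several and left 17109 unnamed, of which none was given a name. Symbols were checked through Entrez IDs against the RefSeq gene table of GRCh38.p14 (30074 probes matched, 39 did not), and that table also gave the order of genes along chromosomes; none of its coordinates are used. A gene was stood for by its tested probe with the highest mean, giving 10886 genes. Of 2850 genes with several tested probes, 81 had probes whose differences lay at least 1 log2 apart.

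Where no array of a group detected a gene, the fold is a bound, computed from the mean normalized log2 value of the brighter group and, for the dimmer group, the mean over its arrays of the higher of the probe's own value and the lowest value of any detected probe. Gene lists were fixed before the data were examined: 31 lists with 559 distinct genes, of which 374 were tested. The 30 lists with at least 3 tested genes were tested with limma's camera (two-sided, preset correlation 0.01, Benjamini-Hochberg over lists), with an estimated correlation and fry as alternatives. The lists around MET and EGFR were chosen from the known position of those genes on chromosome 7. Counts of genes at least 2-fold apart in all 3 lines carry no p-value; they were set against 100 simulated draws of unchanged arrays that share 1 parental array. Differences between single resistant lines were described by size.

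Named genes were chosen by a rule fixed before the data were examined. It takes the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, or, since none passed, those with the largest smallest-of-3 difference that were detected on every array of the higher group; EGFR, ERBB2, ERBB3, MET, AXL, CDH1, VIM and ZEB1 in any case; up to 4 tested members of each list with the largest mean difference; and, for each resistant line, the 4 genes with the largest gap to the nearest other array, detected on the higher side. Entries without a gene name of their own (LOC, HS. and open reading frame symbols) were skipped.

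The code was tested on simulated data before use. With 18695 probes of the real means and variances drawn from the fitted prior, resistant minus parental, limma recovered 1 of 50 probes planted at a log2 difference of 1, 2 of 50 at 2, 41 of 50 at 4 and 50 of 50 at 6, with 4 false calls, so a probe at 4-fold was rarely called with these arrays. For lists, over 10886 simulated genes, camera called a list of 15 genes shifted by 1 log2 and none of the unchanged lists, while with an estimated correlation the planted list was missed (adjusted p = 0.383). A block of shifted neighbouring genes was recovered by the running median used in the closing section. Alternatives tried were the normalization (quantile without background correction, a 75th percentile shift, the authors' values), the detection filter, each resistant line left out, the eBayes settings, array weights, the probe that stands for a gene, a 3-fold size and the list tests. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.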

Results

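Gene expression was measured in HCC827, an established human lung adenocarcinoma cell line that carries an activating mutation of the receptor tyrosine kinase EGFR, and in 3 afatinib-resistant lines derived from it. Afatinib is an irreversible inhibitor of the kinases of the ERBB receptor family. Per the labels, HCC827 cells were grown as tumours under the skin of nude mice, the mice were dosed by mouth with afatinib in steps up to 100 mg/kg, and cells were isolated from tumours that had become resistant. The resistant lines are called BR42, BR16-1 and BR16-2, and the parental cells had not been selected in mice. Total RNA came from cultures at 70% confluence without drug and was hybridised to Illumina HumanHT-12 v4 BeadChips, on which each transcript is read by a probe of human sequence. There was 1 array for the parental cells and 1 for each resistant line, 4 arrays in all, each with 47230 probes. Between 15594 (BR42) and 16285 (BR16-2) probes were detected per array at a detection p under 0.01, and the median signal lay between 142.0 (BR16-2) and 154.6 (parental). For arrays, the number of arrays limits the precision. Values are normalized log2 intensities of a gene's brightest tested probe, and differences are resistant minus parental, with the SD over the 3 resistant lines (n = 3).

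The first question was which genes differ between cells that had become resistant in the animal and the cells they came from. The resistant lines had also been grown in mice and isolated again, and no array holds cells from an untreated tumour. Drug selection and growth in mice therefore cannot be told apart in any difference from the parental cells. The gene most clearly higher in the resistant lines was MSLN, the surface glycoprotein mesothelin: it was not detected in the parental cells and reached 9.79 ± 0.23 (SD, n = 3) in the resistant lines, at least 17.4-fold higher. AXL, a receptor tyrosine kinase, was 10.7-fold higher, at 9.62 ± 0.56 (SD, n = 3) against 6.21. QPRT, an enzyme of NAD synthesis, was at least 9.80-fold higher, and VNN1, a pantetheinase, at least 6.69-fold higher. SLC1A7, a glutamate transporter, was at least 8.13-fold higher, and SLC43A3, another membrane transporter, was 6.85-fold higher. TPM2, an actin-binding tropomyosin, was 9.35-fold higher. TMEM158 was 11.2-fold higher, DNAAF11 9.71-fold higher, ITPRIP at least 7.15-fold higher, SELENOM, a selenoprotein, at least 6.53-fold higher, and HOXB2, a homeobox transcription factor, at least 5.03-fold higher. By the rule that chose them, each of these 12 genes was detected on all 3 resistant arrays and was higher in all 3 lines. "At least" marks a gene not detected on any array of the dimmer group, and these bounds hold for the background-corrected values only. Without background correction the log2 difference was 2.81 for MSLN, where the bound was 4.12, and 1.20 for HOXB2, where the bound was 2.33.

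The largest differences in the other direction were in FGB and FGG, which encode chains of fibrinogen. FGB stood at 12.12 in the parental cells and 5.76 ± 0.63 (SD, n = 3) in the resistant lines, 82.2-fold lower, and FGG was 41.5-fold lower. A second probe gave smaller log2 differences, -4.65 for FGB and -2.29 for FGG, so the size of the fall depended on the probe. SOX2, a transcription factor of stem and progenitor cells, was 15.7-fold lower, with a second probe at a log2 difference of -2.88. GPX2, a glutathione peroxidase, was 15.99-fold lower, and CFI, a protease of the complement system, was 13.9-fold lower. TRPC6, a cation channel, was 18.2-fold lower, IGFBP2, a binding protein of insulin-like growth factors, 9.64-fold lower, RASD1 8.92-fold lower and ASRGL1 8.28-fold lower. CFI was detected on all 3 resistant arrays and ASRGL1 on 2, but FGB, FGG and SOX2 were detected in BR42 only among the resistant lines and GPX2, TRPC6, IGFBP2 and RASD1 in BR16-2 only, so that these folds are approximate and the order of the lines is not resolved. FMO5 was at least 6.35-fold lower, PLEKHS1 at least 5.07-fold lower and SERPINB3, a protease inhibitor, at least 4.83-fold lower, none of them detected on a resistant array. A second SERPINB3 probe gave a log2 difference of -1.43.

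**Figure D1:**
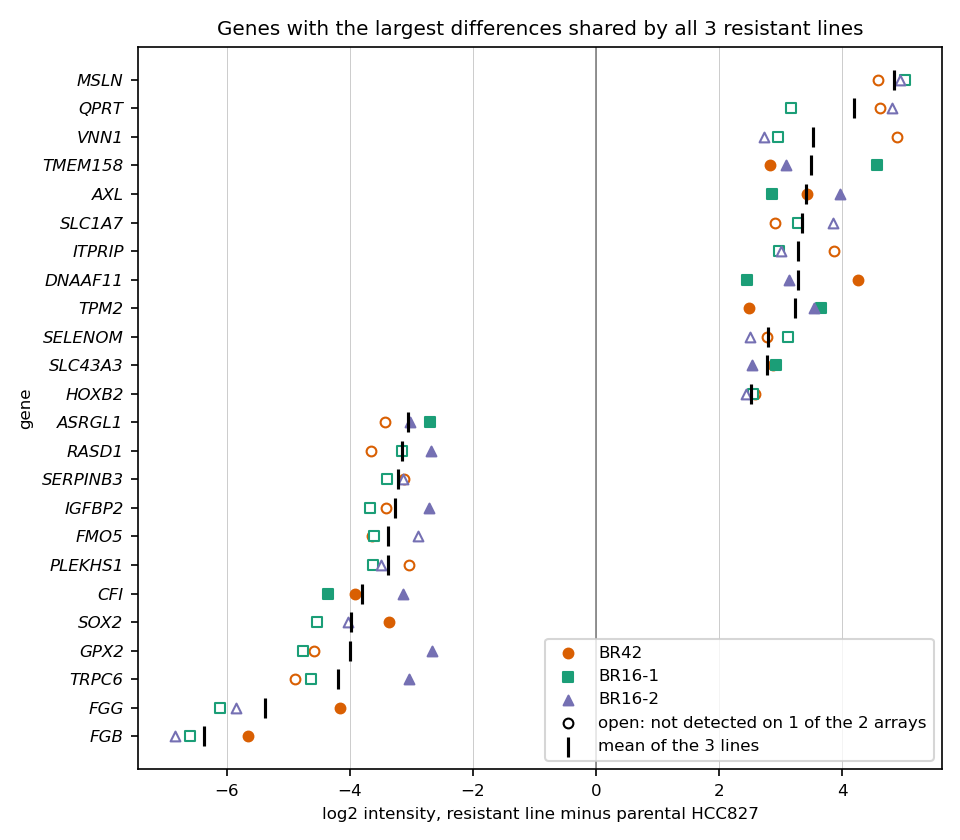
Log2 intensity of each resistant line minus the parental array (horizontal axis) for the 12 genes with the largest shared difference in each direction (vertical axis), with 1 point per line, open where the gene was not detected on that array or in the parental cells, and a bar at the mean of the 3 lines. Open points rest on a value not above background and are approximate. Among genes detected on all 4 arrays the means run from -3.80 for CFI to 3.49 for TMEM158. By the rule that chose the genes, all 3 lines lie on the same side of 0 for each gene.

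None of these genes passed the test. Of 18695 probes tested with limma, 0 were higher and 0 were lower at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.112, for MSLN. At an unadjusted p under 0.05 there were 1259 probes, 516 higher and 743 lower, where 935 would be expected with no effect. By trend and robust settings of limma, 2 probes were higher (MSLN and 1 probe without a gene name) and 2 lower (both FGB); with array weights, which rest on the same few arrays, 52 were higher and 71 lower. By size alone, 108 genes of 10886 were at least 2-fold higher and 156 at least 2-fold lower in all 3 lines, where simulated unchanged arrays that share 1 parental array gave means of 31.6 and 31.5. These counts shrink to 34 and 58 without background correction, which also lowers the log2 difference of 19 of the 24 genes above by more than 1.5 times, and grow to 215 and 313 without BR42; without BR16-1 there were 167 and 191.

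Among the receptors that afatinib targets, EGFR differed between the resistant lines. It was bright in the parental cells (11.99) and in BR42 (11.83), and lower in BR16-1 (9.44) and BR16-2 (9.43), so that its mean difference was -1.75 ± 1.38 (SD, n = 3; limma adjusted p = 0.821). A second bright EGFR probe gave -0.85 in BR42, -2.31 in BR16-1 and -2.79 in BR16-2, so the size of the difference in BR42 depended on the probe. ERBB2 differed by -0.53 ± 0.36 and ERBB3 by -0.32 ± 0.72 (SD, n = 3), both within the spread that the fit allows (limma adjusted p = 0.850 and 0.949). ERBB3 was higher in BR42 (0.49) and lower in BR16-1 (-0.88) and BR16-2 (-0.56), and a second ERBB3 probe gave a mean log2 difference of 0.16. Of the 9 tested ERBB receptors, ligands and feedback inhibitors, 4 were higher and 5 lower on average (camera adjusted p = 0.396). BTC, the ligand betacellulin, was 4.34-fold lower with little spread (-2.06 in BR42, -2.11 in BR16-1 and -2.19 in BR16-2), whereas HBEGF and NRG1, which encode other ERBB ligands, were lower in BR42 and higher in both BR16 lines. BTC was 1 of the genes that passed when adjusted over the list alone. Of 17 genes that report activity of the ERK pathway, 10 were higher and 7 lower (camera adjusted p = 0.286): FOSL1 differed by 1.39, DUSP5 by 1.22 and ETV4 by 1.10, but DUSP4, detected in BR16-2 only among the resistant lines, by -1.20.

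Among receptor tyrosine kinases outside the ERBB family, 5 of 10 tested receptors were higher on average and 5 lower. The list fixed for them also held 2 tested ligands and 2 adaptors, all higher, so that 9 of its 14 genes were higher and 5 lower, with a list median of 0.34, or 0.20 without background correction (limma's camera adjusted p = 0.0468). With an estimated correlation the call was lost (adjusted p = 0.802 with an estimated correlation), and it also ended with the authors' values (adjusted p = 0.0527), without background correction (0.0539) and without BR16-2 (0.0553). MET, the receptor of hepatocyte growth factor, was 2.62-fold higher, with log2 differences of 1.504 in BR42, 1.34 in BR16-1 and 1.33 in BR16-2 (limma adjusted p = 0.350). AXL was the largest of the group, and GAS6, the ligand of AXL, was at least 4.14-fold higher. FGFR3 differed by -1.66, with a second probe at 0.36.

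Most of the genes that lie next to MET on chromosome 7 were higher with it on average. Of 9 tested genes of this neighbourhood, 8 were higher on average and 3 were at least 2-fold higher in all 3 lines: CAPZA2, 3.22-fold higher at 12.99 ± 0.05 against 11.30 (SD, n = 3), TES, 2.95-fold higher, and MET itself. MDFIC was 2.10-fold higher. The list median was 1.504 in BR42, 1.13 in BR16-1 and 0.76 in BR16-2 (camera adjusted p = 0.000105; adjusted p = 0.763 with an estimated correlation), and 4 of the 9 genes passed when adjusted over the list alone. The genes around EGFR, also on chromosome 7, went the other way: all 9 tested genes were lower on average (camera adjusted p = 0.000195; adjusted p = 0.802 with an estimated correlation), with LANCL2 7.83-fold, VOPP1 4.21-fold and NIPSNAP2 2.65-fold lower. Their median was -0.25 in BR42, -1.41 in BR16-1 and -1.76 in BR16-2, so the spread between lines was as large as the difference, and 0 of the 9 passed when adjusted over the list alone.

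**Figure D2:**
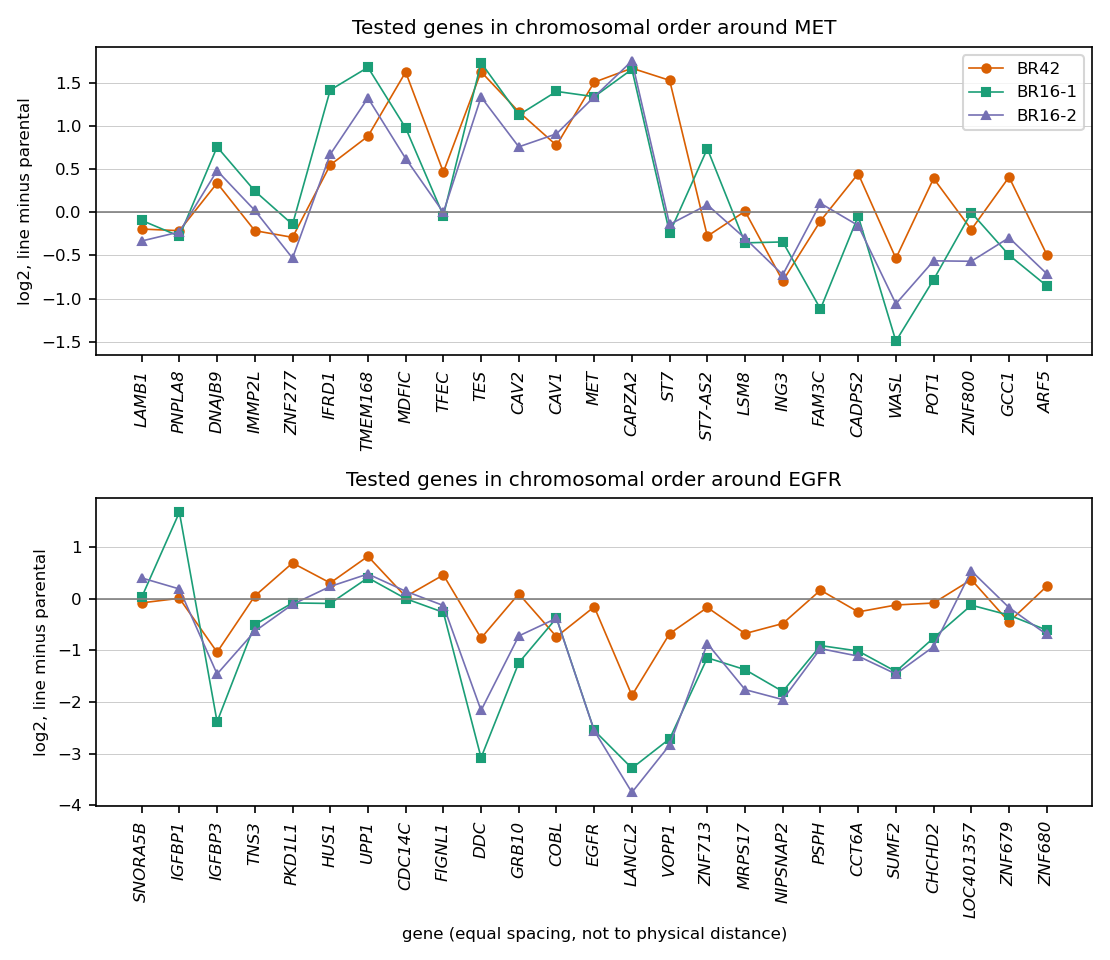
Log2 intensity of each resistant line minus the parental array (vertical axes) for the tested genes in chromosomal order around MET (top) and EGFR (bottom), at equal spacing, with 1 line of points per resistant line. The genes from TES to CAPZA2 lie above 0 in all 3 lines, with MET at 1.504, 1.34 and 1.33; from EGFR to CHCHD2 both BR16 lines lie below BR42, with EGFR at -2.55 in both against -0.15.

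Most of the detected mesenchymal genes were higher on average, and the epithelial genes as a list were not lower. Of 14 tested mesenchymal genes, 11 were higher and 3 lower on average, and AXL, SPARC and VIM were at least 2-fold higher in all 3 lines (list median 0.93, or 0.91 with undetected genes at their bound and 0.61 without background correction; camera adjusted p = 0.00181; adjusted p = 0.763 with an estimated correlation). VIM, the intermediate filament vimentin, was 4.52-fold higher, at 10.22 ± 0.66 (SD, n = 3) against 8.04. SPARC, a matrix protein, was not detected in the parental cells and at least 2.36-fold higher. SNAI2, a transcription factor that represses epithelial genes, was not detected in the parental cells or in BR42 and was detected in both BR16 lines, at least 2.32-fold higher on average over the 3 lines. A second SNAI2 probe gave a mean log2 difference of 0.82. Of 24 listed mesenchymal genes named on the array, 10 were not detected on any array, among them CDH2, FN1, SNAI1, TWIST1, ZEB1 and ZEB2. Over probes detected on all 4 arrays the mesenchymal call ended (adjusted p = 0.0540), and 3 of the 14 genes passed when adjusted over the list alone. Of 25 epithelial genes, 15 were higher and 10 lower (camera adjusted p = 0.396). CDH1, which encodes E-cadherin, stood at 12.73 ± 0.09 (SD, n = 3) against 12.69, CLDN1 differed by 1.41, LSR by 1.05 and OVOL2 by -0.69. Markers of other cell types that a tumour could hold were mixed. Of 14 fibroblast markers 0 were detected on all 3 resistant arrays, with COL1A2 and LUM detected on 1 each, and of 11 endothelial markers 1, PECAM1, was tested and detected on 1. Of 12 leukocyte markers 7 were not detected on any array, and of the 5 tested 4 were higher on average: LYZ, which encodes lysozyme, was not detected in the parental cells and at least 1.37-fold higher, and CSF1R, a receptor of macrophages, stood at 7.04 ± 0.36 (SD, n = 3) against 6.12, both detected on all 3 resistant arrays, whereas CD14 was 2.50-fold lower.

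Genes of sterol and fatty acid synthesis and of the cell cycle were slightly higher. In the first list 16 of 17 tested genes were higher on average and 11 in all 3 lines, with a median of 0.35 (camera adjusted p = 0.000340; adjusted p = 0.802 with an estimated correlation). FASN, fatty acid synthase, was 2.02-fold higher, SQLE 1.86-fold, DHCR7 1.80-fold and MVD 1.80-fold, the last 3 being enzymes of cholesterol synthesis. In the cell cycle list 21 of 25 genes were higher, with a median of 0.30, or 0.29 with bounds (camera adjusted p = 0.0116; adjusted p = 0.802 with an estimated correlation; 0.0603 without BR16-1). MCM2, a subunit of the replicative helicase, was 2.21-fold higher and UBE2C, a ubiquitin-conjugating enzyme of mitosis, 1.68-fold, while E2F1 was 1.72-fold lower. MKI67 was detected on 1 of the 3 resistant arrays only. In both lists 0 genes passed when adjusted over the list alone.

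Targets of the oxidative stress factor NRF2 and genes of drug transport and metabolism were lower. Of 18 tested NRF2 targets, 14 were lower on average and 4 were at least 2-fold lower in all 3 lines (median -0.64; camera adjusted p = 0.000574; adjusted p = 0.763 with an estimated correlation), with 2 that passed when adjusted over the list alone. Besides GPX2, the aldo-keto reductases AKR1C3 and AKR1B10 were 6.19-fold and 5.43-fold lower, and ABCC2, an efflux transporter, was 3.885-fold lower. Of 12 tested genes of drug transport and metabolism, 10 were lower (median -0.43, or -0.21 without background correction; camera adjusted p = 0.00816; adjusted p = 0.763 with an estimated correlation). CYP1A1, a cytochrome P450 enzyme, was not detected in the resistant lines and at least 2.17-fold lower. CYP1B1, another one, was lower in both BR16 lines (-3.30 and -2.87) and 0.08 apart in BR42. ABCC3 was 3.62-fold lower. ABCC2 and ABCC3 belong to both lists.

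The other lists did not pass camera. Of 22 interferon response genes 19 were higher on average (adjusted p = 0.0555): IFI27 was 6.78-fold, OAS2 at least 3.37-fold, IFITM1 4.09-fold and OAS3 2.07-fold higher, but the list median was 0.70 in BR42, -0.31 in BR16-1 and 1.16 in BR16-2. The other tested OAS2 probes gave log2 differences of 0.52 to 1.01. Of 16 antigen presentation genes 11 were higher (adjusted p = 0.150), CD74 at least 2.76-fold and HLA-B 2.94-fold, while HLA-DMB was 2.71-fold lower. Of 7 lung alveolar and airway genes, 4 were lower (adjusted p = 0.150): NAPSA, the aspartic protease napsin A, was 5.40-fold lower, MUC1 4.32-fold and FOXA1 2.58-fold lower, and FOXA2 2.11-fold higher. Of 13 TGF-beta targets 10 were lower (adjusted p = 0.117), ID3 3.01-fold. Of 18 hypoxia and glycolysis genes 12 were lower (adjusted p = 0.231), EGLN3 4.02-fold, though it was not detected in BR42. Among 9 stem-like genes 5 were higher (adjusted p = 0.728), with SOX9 at least 4.46-fold higher beside the lower SOX2; the list median was 0.29 and its test pointed up, but its mean was -0.12. Of 13 invasion and adhesion genes 7 were higher and 6 lower (adjusted p = 0.498), with CEACAM6 at -1.12 in BR16-2 and not detected in BR42 and BR16-1, and MMP7, detected in BR42 only among the resistant lines, 5.596-fold lower on average; the list median was 0.03 (0 with undetected genes at their bound), its mean -0.20 and its test pointed up.

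None of the remaining tested lists passed camera either. Adjusted p was 0.0837 for 19 YAP targets (13 higher; IGFBP3 3.08-fold lower), 0.117 for 21 NF-kB targets and cytokines (14 higher), 0.179 for 15 genes of ATF4 and the unfolded protein response (10 higher; PHGDH 4.53-fold) and 0.207 for 17 apoptosis regulators (13 higher; BID at least 2.22-fold, with its other tested probes at log2 differences of 0.01 to 0.93). It was 0.957 for 6 WNT targets (4 higher; DKK1 at -1.22 in BR42 and 2.71 and 2.49 in the BR16 lines), with a positive median of 0.11 (0.01 with bounds) and a test that pointed down, and 0.948 for 8 Notch pathway genes (5 higher; HES4 0.45 and JAG1 -0.40). For lineage markers it was 0.494 for 7 squamous genes (5 higher; KRT16 2.61-fold lower), 0.286 for 4 neuroendocrine genes (2 higher; DDC -0.76 in BR42, -2.16 in BR16-2 and not detected in BR16-1) and 0.0786 for 3 cancer-testis antigens (3 higher, with a median of 0.58, or 0 with bounds; PRAME 2.20-fold, the other 2 detected on 1 resistant array each). It was 0.957 for 3 fibroblast markers, with a positive median of 0.16 (0 with bounds) and a test that pointed down, 0.154 for 5 leukocyte markers (4 higher) and 0.728 for 8 housekeeping genes, whose median was -0.02 with the mean and the test above 0 (ACTB 0.26). Over all lists, 17 list entries passed when adjusted over the list alone, against 0 over all probes. Without background correction the medians given above also moved to 0.17 for the stem-like, 0.09 for the invasion, 0.03 for the WNT, 0.21 for the cancer-testis and 0.05 for the fibroblast list. The camera calls assume a preset correlation of 0.01 between genes. Of the 8 lists past it, 0 held with an estimated correlation, and fry, which tests whether a list moves one way, called 0. With an estimated correlation camera also missed the planted list of the simulation, so that loss cannot decide whether a list changed. The estimate lay below the preset for the mesenchymal (-0.037), NRF2 (-0.016) and drug (-0.060) lists. For the other lists past camera it ran from 0.030 to 0.986.

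**Figure D3:**
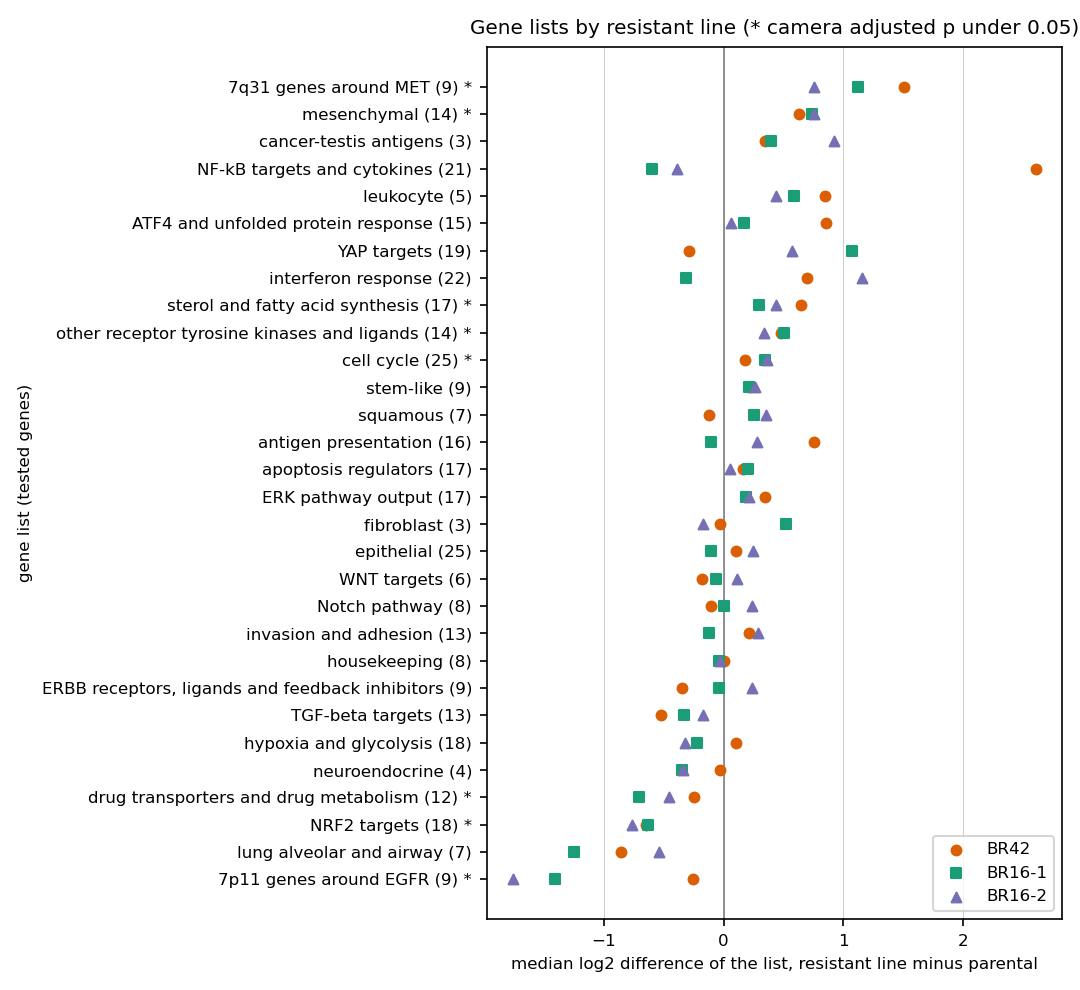
Median log2 difference from the parental array (horizontal axis) of each gene list with at least 3 tested genes (vertical axis, number of tested genes in brackets), with 1 point per resistant line and an asterisk on the 8 lists past camera. The NF-kB list spans 2.61 in BR42 to -0.60 in BR16-1, the widest gap between lines, while the NRF2 list lies between -0.76 and -0.63 in all 3.

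The resistant lines also differed from each other, which was described by size since each has 1 array. BR16-1 and BR16-2 were nearest, with an SD of their difference over genes of 0.474 and 462 genes at least 2-fold apart. BR42 lay farther from both, at 0.737 and 1287 genes from BR16-1 and 0.600 and 771 genes from BR16-2, which is as far as the parental array lay from the resistant lines (0.657 from BR42, 0.717 from BR16-1 and 0.614 from BR16-2). Against the parental array, 515 genes were at least 2-fold higher and 432 lower in BR42, 469 and 675 in BR16-1, and 391 and 432 in BR16-2. BR16-1 and BR16-2 shared 215 of the higher genes and 311 of the lower ones, where independent lists would share 16.8 and 26.8, and 3 genes went opposite ways. BR42 shared 140 higher and 221 lower genes with BR16-1 (22.2 and 26.8 for independent lists), with 50 in opposite directions, and 167 and 192 with BR16-2 (18.5 and 17.1), with 19 opposite. Across genes, which are not independent replicates, the differences correlated at 0.76 between the BR16 lines, 0.56 between BR42 and BR16-2 and 0.43 between BR42 and BR16-1. Simulated pairs of unchanged lines that share the parental array gave a mean correlation of 0.50, between 0.456 and 0.539. The value for BR42 and BR16-1 was no higher, but differences between 2 lines lower a correlation. It therefore cannot decide whether these lines share changes. The same simulated pairs shared 63.6 higher genes (40 to 85) and 63.7 lower genes (42 to 87) on average, with 9.19 opposite (1 to 19), and part of each overlap may come from that array. Each observed overlap of higher or lower genes lay above these ranges. The simulated parental array varied like the lines, and a larger deviation of the real one was not tested. The covariance of the differences was 0.333 between the BR16 lines, 0.225 between BR42 and BR16-2 and 0.202 between BR42 and BR16-1, against a simulated mean of 0.118.

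Cytokine genes set BR42 apart. The median of the 21 NF-kB targets and cytokines was 2.61 in BR42, -0.60 in BR16-1 and -0.39 in BR16-2, and 17 of the 21 were at least 2-fold lower in the BR16 mean than in BR42. IL1A, the cytokine interleukin-1 alpha, differed from the parental array by 5.25 in BR42 and was not detected in the BR16 lines. CXCL6, a chemokine, differed by 4.50 in BR42 and -0.05 in BR16-2 and IL1B by 4.21 and -0.71, neither detected in BR16-1, and SAA1, an acute-phase protein, by 4.36 in BR42, -0.61 in BR16-1 and 0.21 in BR16-2. TNFAIP3, a feedback inhibitor of NF-kB signalling, was higher in each line, at 1.08, 2.01 and 1.48 in the same order. SLC2A3, a glucose transporter, was detected in BR42, at 10.12, and on no other array. Of 16 antigen presentation genes, 15 were lower in BR16-1 than in BR42 (median -0.88), but in BR16-2 10 were lower and 6 higher (median -0.28). YAP targets ran the other way: 16 of 19 were higher in the BR16 mean than in BR42, 9 of them at least 2-fold, and CCN2, a secreted YAP target, differed from the parental array by 3.07 in BR16-1 and 1.83 in BR16-2 and was not detected in BR42.

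Of genes far from every other array in BR16-1, DEFB4A, LCN2, S100A9 and DEFB1 were lower there and higher in BR42 than in the parental cells. LCN2, the iron-binding lipocalin, differed from the parental array by 2.06 in BR42, -3.80 in BR16-1 and -0.42 in BR16-2. DEFB4A, a beta-defensin, differed by 4.18 in BR42 and 0.41 in BR16-2, S100A9, a calcium-binding protein, by 2.26 and -1.72, and DEFB1, another beta-defensin, by 2.37 and -0.72; these 3 were detected in the parental cells and not in BR16-1. In BR16-2, LGALS4, a galectin, was higher by 4.42 than in the nearest other array, and ANO1, a chloride channel, by 2.68. ADH1A, an alcohol dehydrogenase, was detected in BR16-2 only, and LMBR1 on every array but BR16-2. These differences between single arrays have no replicate check. All 9 tested genes around EGFR were lower in the BR16 mean than in BR42, 6 of them at least 2-fold, with a median of -1.31, where the 502 genes of chromosome 7 outside the stretch around EGFR had a median of -0.26 and those of the other chromosomes together 0.04; chromosome X stood apart in the other direction, at 0.27 over 370 genes.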

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

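The mean of both BR16 lines as 1 replicate was chosen after seeing the data; the other settings were planned. Of 1401 gene values under these settings, 1358 kept their direction and side of the threshold, 28 passed only under array weights (25), trend and robust eBayes (2) or a 75th percentile shift (1), and 15 reversed. No gene had passed in the main fit, so no call could be lost, and many genes were picked for a large difference. The share that stayed the same is therefore no measure of robustness. The count of 0 called probes moved to 1 lower with a 75th percentile shift, 2 higher and 2 lower with trend and robust eBayes, and 52 higher and 71 lower with array weights, whose weights ran from 0.37 to 3.30; the largest went to BR16-2. It stayed at 0 with each line left out in turn. Counts at least 2-fold apart in all 3 lines (108 higher, 156 lower) were 34 and 58 with quantile normalization without background correction, 35 and 61 with a 75th percentile shift, 36 and 61 with the authors' values, 52 and 66 over probes detected on all 4 arrays, 44 and 57 at 3-fold, and 140 to 215 and 191 to 313 with each line left out in turn (fewer lines to satisfy). Background left in the signal shrinks differences of dim probes. Of the genes, 34 of the 34 and 58 of the 58 without background correction were among the 108 and 156. The 8 lists past camera became 0 with an estimated correlation, 0 with fry and 15 with the BR16 mean as 1 replicate; the cause was not tested. With each line left out there were 11 to 12. The SD between lines moved to 0.480 (BR42 and BR16-1), 0.386 (BR42 and BR16-2) and 0.290 (BR16-1 and BR16-2) without background correction, 0.483, 0.383 and 0.292 with a 75th percentile shift, 0.489, 0.393 and 0.296 with the authors' values, and 0.570 for BR42 and BR16-1 with no detection filter. Of the reversed genes, none past the threshold under any of these settings, the mean log2 difference with each line left out ran from -0.0081 to 0.081 for CDH1 (lowest without BR16-2), and, lowest without BR42, from -0.18 to 2.22 for CXCL6, -0.57 to 2.35 for IL1A, -0.20 to 2.29 for SAA1, -1.28 to 1.75 for IL1B and -1.74 to 2.29 for DEFB4A. It ran, highest without BR16-1, from -2.11 to 0.82 for LCN2, -3.34 to 0.27 for S100A9 and -2.09 to 0.82 for DEFB1, and from -0.59 (without BR16-2) to 2.18 for LGALS4. CDH1 was -0.026 with a 75th percentile shift, IL1A -0.047, IL1B -0.43 and COL1A2 -0.044 with array weights, and DEFB1 0.14 with the BR16 mean. Apart from CDH1 and COL1A2, whose differences are near 0, these are genes whose mean rests on 1 line or on lines that went opposite ways. The latter holds for DEFB4A, LCN2, S100A9, DEFB1 and IL1B. The chip as a block was not run, because the files name no chip. No paired analysis was possible because the parental group has 1 array and the replicate numbers only name the lines. Signal over background limits the folds: genes undetected in a group have only a bound, which holds for the background-corrected values only.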

Other observations

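All tests in this part were chosen after the results were seen. Running medians over 15 neighbouring genes, set against 1000 shuffled gene orders over 10874 genes, picked out further stretches of chromosome whose genes differed together in the median. Their end genes are named here because of these values. A stretch covers all genes of its windows past the threshold, so its end genes are window margins and need not differ themselves. On chromosome 14 the 33 genes from TIMM9 to EIF2S1 had medians below 0 in all 3 lines, -0.65 in BR42, -0.49 in BR16-1 and -0.46 in BR16-2. On chromosome 3 the 29 genes from MYLK to RAB43 had a higher median in BR42 (0.78) than in BR16-1 (0.22) and BR16-2 (0.33). On chromosome 7 the 31 genes from GNB2 to RPL19P12 had a median of 0.83 in BR42 against 0.18 and 0.15, and the 23 genes from GATAD1 to LMTK2 one of -0.76 in BR16-1 and -0.55 in BR16-2 against -0.20 in BR42. Between BR42 and the mean of the BR16 lines 73 windows in 9 stretches passed the threshold. Of the 9 stretches 7 lie on chromosome 7, and all 9 were lower in the BR16 lines than in BR42, though not all were lower than in the parental cells.

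The list median of the genes around MET was above 0 in all 3 lines, and 6 of the 9 tested genes were higher in each line. ST7, next to CAPZA2, was higher in BR42 (1.53) and not in BR16-1 (-0.24) or BR16-2 (-0.14). The running median at MET reached 0.88 in the mean of the lines, and no shuffled order gave as large a value anywhere (permutation p = 0.001, the smallest that 1000 shuffles can give); in single lines it passed in BR42 (p = 0.03) and BR16-1 (p = 0.009) and not in BR16-2 (p = 0.3). Scaling between arrays does not account for it, since the list median stayed at least 0.89 above that of all genes under 4 scalings. A deviation of the single parental array cannot be told apart from a change in the lines, because the smallest of the 3 list medians was 0.76 and no second parental array exists here. A gain of this segment in the resistant lines, known as a route of resistance to EGFR inhibitors in this cell line, may be a candidate explanation; DNA was not measured.

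The genes around EGFR were lower in both BR16 lines than in BR42; this comparison leaves out the parental array, so a deviation of that array is excluded as its cause (list median -1.31, 9 of 9 genes below 0). The stretch covers 29 genes, from IGFBP1 to CCT6P1, of which 79.3% were lower. Its end genes are margins of the windows, and IGFBP1 itself was not lower. No shuffled order gave as large a running median (permutation p = 0.001), which argues against each gene differing independently of its neighbours. The shuffles do not show what made neighbours differ together. The stretch is part of a wider pattern. The 502 genes of chromosome 7 outside it had a median of -0.26 (66.3% lower) and the stretch itself -0.76, against 0.04 on the other chromosomes together. Chromosome X, at 0.27 over 370 genes (27.6% lower), stood as far apart in the other direction. Between BR16-1 and BR16-2, 0 windows passed the threshold, against 43 between BR42 and BR16-1 and 59 between BR42 and BR16-2, which is consistent with segments shared by both BR16 lines. Against the parental array, the stretch at EGFR had a median of -0.15 in BR42, -0.76 in BR16-1 and -0.72 in BR16-2. The stretch from SLC12A9 to POLR2J3 on chromosome 7 instead stood at 0.88, 0.19 and 0.21. There, a rise in BR42 or a deviation of its single array cannot be told apart from a fall in the BR16 lines. HCC827 is known to carry extra copies of EGFR, and fewer copies of this segment, of a larger part of chromosome 7 or of both in the BR16 lines may explain the pattern at EGFR as a hypothesis. DNA was not measured, and a shared origin of these 2 lines stays open and untested.

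Most of the detected mesenchymal genes were higher on average in the resistant lines, which had grown in mice. Mouse stromal cells carried over from the tumours, whose RNA probes of human sequence would read only in part, would bring collagen and other abundant fibroblast transcripts, but 0 of 14 fibroblast markers were detected on all 3 resistant arrays: COL1A1 reached at most 5.31 and COL3A1 5.20, where the lowest detected probe stood at 5.65 to 5.76, and COL1A2 (at most 6.14) and LUM (5.91) were detected on 1 resistant array each. Leukocytes would bring their abundant transcripts too, but 7 of 12 markers were not detected on any array, among them PTPRC, TYROBP and FCER1G, named after their values were seen. Of the 5 others 4 were higher on average, with LYZ and CSF1R higher in all 3 lines, and CD14 was lower. Since human probes read mouse RNA only in part, undetected markers cannot exclude carried-over mouse cells of either kind. Scaling between arrays is argued against, since the list median stayed at least 0.59 above that of all genes under 4 scalings. A change of state in the cells themselves and a deviation of the parental array may both explain the higher mesenchymal genes, and the second was not tested. Growth in mice, shared by all 3 lines, cannot be told apart from drug selection as the source of such a change.

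Each array was also set against the 3 others. With the parental array alone, 264 genes were at least 2-fold apart from all the others, and the highest of the other splits, BR42, gave 247. As many as 264 genes came from 1 of the 4 splits, the real one, and 4 splits are too few for a share under 0.05. BR16-1 gave 176 genes and BR16-2 gave 38.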
